A study of Mus musculus with 28 samples.

How the data were processed

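RNA was measured in liver tumours that grew from human MCF7 breast cancer cells, carrying the ESR1 mutation Y537S, in NOD scid gamma mice. Per the labels, the 28 libraries fell into 7 groups of 4: vehicle (Vehicle), the estrogen receptor degrader fulvestrant (Fulv), the CDK4 and CDK6 inhibitor palbociclib (Palb), the NAMPT inhibitor KPT-9274 (NAMPTi), and the pairs Fulv+Palb, Fulv+NAMPTi and Palb+NAMPTi. Per the labels' protocols, RNA was extracted with TRIzol and the libraries were made with a stranded mRNA kit. The labels do not say whether the libraries of a group came from separate mice, so the p-values measure the spread between these samples.

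The authors deposited 1 table of raw counts per gene, with a column for each of the 28 libraries. Its values were whole numbers, on 60708 human and 55416 mouse Ensembl IDs. Per the submitters' processing notes, the tools used were FastQC, Trimmomatic 0.38, STAR, Subread 1.6.3, edgeR 3.24.3 and limma, and the genomes were the human GRCh37 (hg19) and mouse GRCm38 (mm10). The notes give no role or order of these tools, and the filters and the strand setting of the counting are not recorded. How reads that match both genomes were assigned is not recorded, so genes with close copies, within a species or across the 2, are uncertain. That holds for the Cyp, Mup and Sult families named in the report.

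Mouse gene names came from a reference annotation of another version than the one behind the table. Of the mouse IDs, 52083 matched without the version suffix and 35 with it, so no coordinates are given. IDs without a match held 0.0541% of the mouse counts. No source at hand paired the human IDs with names. Human genes are therefore counted and not named, the 21 lists of human genes fixed before the data were examined were not tested, and the drug targets among the human genes have no value here. Transcript lengths were those of the longest transcript of each gene in the mouse reference transcripts. No human lengths were used. A library's slope on transcript length is therefore that of its mouse genes, also in fits of human genes.

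Human and mouse genes were fitted apart, each with library sizes summed over its own species, so that the share of mouse tissue did not set the tumour values. The tools were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. The edgeR fit used TMM factors, the default low-count filter on the 7 groups, 1 mean per group and the quasi-likelihood test. It left 18003 human and 14284 mouse genes, and 14261 of the mouse genes had a symbol. A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes of its species. CPM values are counts scaled to the library's total for that species after multiplying that total by the library's TMM factor. The mean log2 CPM of a gene list used a prior count of 2. The comparisons with Vehicle, the human comparisons of a pair of drugs with 1 of them, the interaction terms, the gene lists, the tests and most alternatives were fixed before the data were examined. The mouse comparisons of a pair of drugs with 1 of them were added after it was seen that human genes could not be named.

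Gene lists for mouse cell types and pathways were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation. Lists with fewer than 5 tested members were left out, which left 16 of 17. The genes named were, by rule, up to 4 members past the test from each list that passed or had 3 or more such members, at most 2 members with the smallest p from a list with none, and up to 8 genes per direction with the largest fold change. The last group needed a mean of at least 5 CPM in the higher group and no overlap between the 4 libraries of each group. Genes named outside the rule are marked as chosen after their values were seen. For genes without counts in a group, the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts it is a ratio with its 95% counting interval. These bounds and intervals cover counting error alone, since reads without molecular identifiers are not independent molecules. The share of counts on human genes was compared by an exact two-sided permutation test of each treated group with Vehicle.

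The fit was tested on simulated counts, drawn for each gene apart from its mean over all 28 libraries. In Fulv 200 genes were changed and, besides, 1 gene list was raised 2-fold. edgeR called 8.96% of human and 4.48% of mouse genes changed 1.5-fold, 37.3% and 35.8% of those changed 2-fold, and 81.8% and 86.4% of those changed 4-fold. Of its calls, 5.94% in human and 5.26% in mouse genes were false. DESeq2 had 20.7% and 12.2% false calls, and limma-trend 8.41% and 6.06%. Camera called the raised list and none of the 15 unchanged ones in either species. The simulated genes were independent, while the estimated correlation within a real list reached 0.85 (hepatocytes, Fulv against Vehicle). The simulation therefore does not show how often camera or edgeR calls falsely where genes move together.

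The alternatives were DESeq2's test, RLE factors in edgeR, no low-count filter, limma-trend, the replicate number as a block, the log2 ratio of human to mouse counts as a covariate, a fit of the compared groups alone, and each library left out in turn. Other alternatives were chosen after seeing the data: the hepatocyte list mean as a covariate, each library's slope on transcript length as a covariate, that length trend removed, and the fit without Vehicle 3 and 4. The replicate number was not taken to pair the samples: in none of the 9 comparisons did all 4 same-number pairs correlate at over 0.1 across genes of either species. In human genes all 4 were positive in Palb against Vehicle, with a lowest correlation of 0.0576, and in Palb+NAMPTi against Palb, with a lowest of 0.0028. No library was left out of the main comparisons. No library had under 1000000 counts of either species.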

Results

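The deposited counts describe 28 liver tumours of MCF7 cells with the ESR1 mutation Y537S, grown in immunodeficient mice and treated with Vehicle, Fulv, Palb, NAMPTi, Fulv+Palb, Fulv+NAMPTi or Palb+NAMPTi, with 4 libraries per group. Total counts per library ranged from 25461740 to 33945493. Human genes, which stand for the tumour cells, took 17331053 to 30121190 counts, and mouse genes, which stand for the host liver and stroma, took 2328224 to 11883091. Per the labels, fulvestrant was given at 100 mg/kg by injection, and palbociclib at 50 mg/kg and KPT-9274 at 100 mg/kg by gavage. The labels give 4 weeks of treatment for the groups with fulvestrant and no duration for the others. The series title places the study in NAD metabolism as a weak point of endocrine-resistant breast metastases.

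The share of counts on human genes was 73.0% ± 7.19 (SD, n = 4) in Vehicle. It was 89.1% ± 3.23 in Fulv, 67.6% ± 4.45 in Palb, 86.0% ± 6.94 in NAMPTi, 80.5% ± 7.18 in Fulv+Palb, 75.4% ± 6.65 in Fulv+NAMPTi and 73.1% ± 3.86 in Palb+NAMPTi (SD, n = 4 each). Fulv was 16.1 percentage points above Vehicle, with an exact two-sided permutation p of 0.02857, the smallest that 70 permutations allow. NAMPTi was 13.0 points above, with an exact permutation p of 0.05714. Adjusted over the 6 comparisons, both exact permutation p-values were 0.1714, so no difference in share passed. The differences of Palb, Fulv+Palb, Fulv+NAMPTi and Palb+NAMPTi were -5.40, 7.53, 2.38 and 0.115 points, with adjusted exact permutation p-values of 0.4286, 0.4, 0.8229 and 1.

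**Figure D1:**
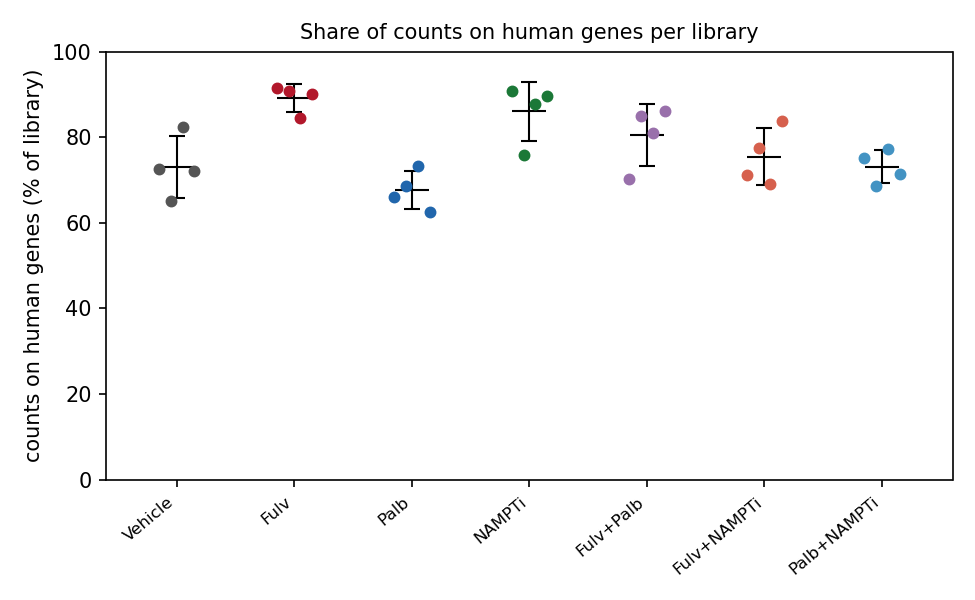
Share of counts on human genes in percent (y axis) for each library by treatment group (x axis), with the mean and SD of 4 libraries per group. Group means ran from 67.6% in Palb to 89.1% in Fulv.

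In the tumour cells, the main divide lay between libraries with and without fulvestrant. The labels give a duration of treatment for the first of these alone, so a difference in duration along this divide is not excluded. On the first principal component of human log2 CPM, which held 37% of the variance, the 12 libraries with fulvestrant lay between -71.5 and -28.7 and the 16 others between 12.2 and 73.6. Vehicle 3 and 4 stood apart from Vehicle 1 and 2 on the second component, which held 11.1%.

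The comparison of Fulv with Vehicle asked how tumour and host tissue differed under estrogen receptor degradation. In the mouse tissue, liver genes with a known sex bias moved in opposite directions. Cyp4a12a, a fatty acid hydroxylase of male liver, rose by 6.20 ± 1.3 on the log2 scale (SE; edgeR adjusted p = 0.011), from 0.269 ± 0.135 to 19.4 ± 19.1 CPM (SD, n = 4). Mup20, a male-biased urinary pheromone protein, rose by 3.79 ± 0.77 (SE; edgeR adjusted p = 0.0071), from 9.21 ± 7.72 to 127 ± 70.7 CPM (SD, n = 4). Sult3a1, a sulfotransferase of female liver, had a log2 fold change of -8.56 ± 1.6 (SE; edgeR adjusted p = 0.0055), from 175 ± 99.3 to 0.49 ± 0.282 CPM (SD, n = 4). A1bg was at least 124-fold lower, Sult2a2 at least 65.9-fold lower and Cyp3a16 at least 55.8-fold lower, each with no count in Fulv. Cyp2c40 was lower by a ratio of 401 (95% counting interval 71.7 to 15800) and Cyp3a41a by 76.8 (21.1 to 636). Vehicle 2 held much of these counts: without it the bounds were 22.5 for A1bg and 14.4 for Cyp3a16, and the ratios 162 for Cyp2c40 and 43.8 for Cyp3a41a. Without Fulv 3 the bounds were 80.9 for A1bg, 43 for Sult2a2, 36.4 for Cyp3a16 and 87.1 for Cyp2c40, and the ratio of Cyp3a41a was 50.1. Without Fulv 1 Cyp3a41a had a bound of 42.2. Of 2 lists of sex-biased liver genes drawn up after the data were seen, 5 of 13 male-biased genes rose, with a median log2 fold change of 1.85, and 17 of 18 female-biased genes fell, with a median of -6.06, or -5.69 with the 4 genes at 0 set at their bound. Members of both lists were among the genes that prompted them, so these counts are no independent evidence of direction.

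Among the lists fixed beforehand, many liver functions had lower medians in Fulv. Xenobiotic metabolism had 3 of 16 genes lower (4 adjusted over the list alone), among them the female-biased Cyp2b9 with a log2 fold change of -3.22 ± 0.76 (SE; edgeR adjusted p = 0.016), and camera gave an adjusted p of 0.0082 (0.52 with an estimated correlation). Fatty acid oxidation had 2 of 16 lower, Cyp4a10 by -4.95 ± 1.2 (SE) and Cyp4a14 by -4.56 ± 1.2 (camera adjusted p = 0.0021, and adjusted p = 0.52 with an estimated correlation). In the acute phase list Fgl1 (-1.71 ± 0.47, SE) and Apcs fell, 2 of 15 genes (camera adjusted p = 0.0021, and adjusted p = 0.52 with an estimated correlation). Arg1, a urea cycle enzyme, was the 1 gene of 14 that fell in the gluconeogenesis and amino acid list (4 adjusted over the list alone; camera adjusted p = 0.00096, and adjusted p = 0.52 with an estimated correlation). Marco, a receptor of resident macrophages, was the 1 of 13 macrophage genes that fell (camera adjusted p = 0.0026), and Irf7 (-0.84 ± 0.22, SE) and Usp18 were the 2 of 20 interferon genes (camera adjusted p = 0.001; both lists at an adjusted p of 0.52 with an estimated correlation). The cell cycle list had 2 of 22 genes higher (6 adjusted over the list alone), the proliferation marker Mki67 by 0.98 ± 0.29 and the replication helicase gene Mcm2 by 0.76 ± 0.19 (SE; camera adjusted p = 3.2e-05), and Fbn1 was the 1 of 14 fibroblast genes that rose (3 adjusted over the list alone; camera adjusted p = 0.014; both lists at an adjusted p of 0.52 with an estimated correlation). No hepatocyte gene passed in edgeR, of 17, with a median of -1.15 (camera adjusted p = 0.00084), and none of 20 NAD genes, with a median of -0.50 (camera adjusted p = 0.025). Their adjusted p-values with an estimated correlation were 0.52 and 0.55. Beside these lists, the hepatocyte mean was 10.6 ± 0.581 log2 CPM in Fulv and 11.5 ± 1.17 in Vehicle (SD, n = 4), and the human share was 89.1% against 73.0%. With the human to mouse ratio as a covariate, camera's adjusted p was 0.76 for cell cycle, 0.85 for acute phase, 0.075 for macrophages and 0.14 for fatty acid oxidation. The hepatocyte, gluconeogenesis, NAD, xenobiotic and fibroblast lists then passed in the opposite direction. Of the lists that had passed before, the interferon list alone passed in the same one (camera adjusted p = 2.8e-08). Lists that had not passed before then did. The neutrophil and ATF4 stress response lists were lower (camera adjusted p = 0.00088 and 0.044), and cholesterol and fatty acid synthesis was higher (camera adjusted p = 0.00023).

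For Fulv against Vehicle edgeR called 5281 human genes, 2283 higher and 2998 lower, and 1353 mouse genes, 702 higher and 651 lower. The files pair no human ID with a name. ENSG00000239402.3 rose by 5.67 ± 0.92 (SE; edgeR adjusted p = 0.00023) and ENSG00000198788.9 by 5.60 ± 1.4 (SE; edgeR adjusted p = 0.0035), while ENSG00000162892.16 had a log2 fold change of -9.0 ± 1.4 (SE; edgeR adjusted p = 0.00019) and ENSG00000162891.11 one of -8.94 ± 1.3 (SE; edgeR adjusted p = 7.4e-05). Of the 30 mouse results of genes named by rule here, 12 passed whichever library was left out, and the mouse count was 424 without Vehicle 4 (196 higher, 228 lower), 228 without Fulv 2 (166 higher, 62 lower), 474 without Fulv 3 (328 higher, 146 lower) and 492 without Fulv 4, while the human count was 3394 without Vehicle 3. In edgeR fits the mouse count was 0 with the length slope as a covariate and 21 with the compared groups alone. The slope was -0.00564 or higher in Fulv and -0.245 or lower in Vehicle, so that fit cannot tell a length trend from an effect of the drug. With the human to mouse ratio as a covariate the mouse count was 1627, with 555 higher and 1072 lower, but 322 of the 1353 calls were among them (23.8%).

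**Figure D2:**
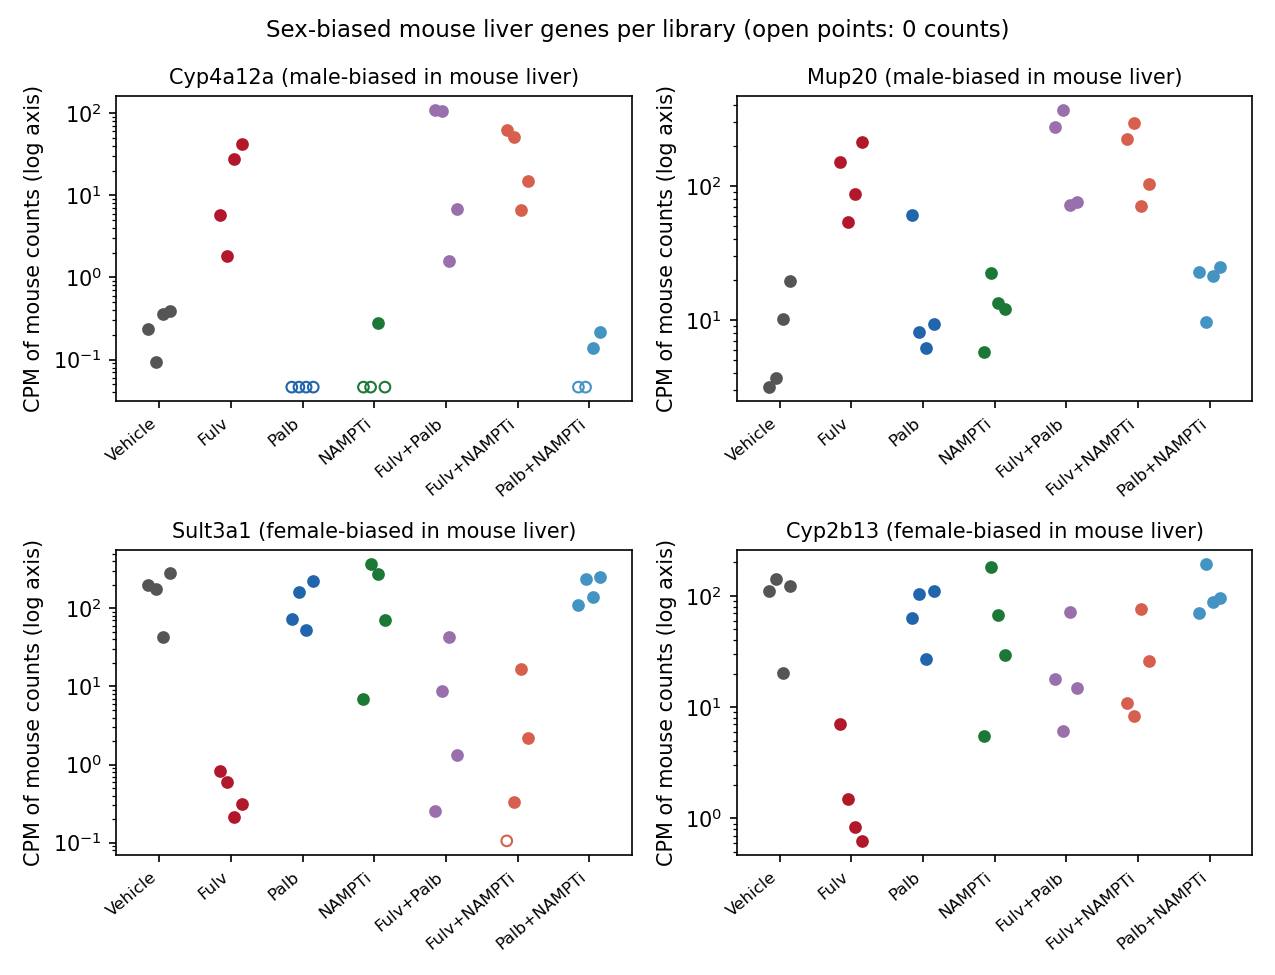
CPM of mouse genes (log y axis) of Cyp4a12a, Mup20, Sult3a1 and Cyp2b13 in each library by group, with open points for libraries at 0 counts drawn below the lowest value. Cyp4a12a lay between 1.57 and 108 CPM in the 12 libraries with fulvestrant and between 0 and 0.39 CPM in the others.

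Palb against Vehicle asked the same of the cell cycle inhibitor alone. In the host tissue, 5 of 20 genes of cholesterol and fatty acid synthesis rose (6 adjusted over the list alone). Fasn, the fatty acid synthase, rose by 2.19 ± 0.45 on the log2 scale (SE; edgeR adjusted p = 0.0033), from 88.0 ± 29.7 to 401 ± 179 CPM (SD, n = 4). Pcsk9, which lowers the LDL receptor, rose by 1.46 ± 0.42, Acly by 1.12 ± 0.32 and Acaca by 1.10 ± 0.33 (SE; edgeR adjusted p = 0.022, 0.022 and 0.028). Camera gave the list an adjusted p of 2e-06, and it was 0.92 with an estimated correlation. Macrophage genes fell in 3 of 13 cases (4 adjusted over the list alone), Lyz2 by -1.49 ± 0.42 and the complement genes C1qb by -1.09 and C1qa by -0.99 (camera adjusted p = 0.42). The homeodomain-interacting kinase gene Hipk2 rose by 1.96 ± 0.26 (SE; edgeR adjusted p = 3e-04) and the transcription factor gene Zbtb16 by 2.47 ± 0.63 (SE; edgeR adjusted p = 0.012), while the ribosomal protein genes Rps14 (-2.15 ± 0.33, SE) and Rpl39 (-1.85 ± 0.34, SE) fell.

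The palbociclib calls went with transcript length, and those of other groups did too. In Palb, mouse genes called higher had a median transcript of 6575 bases, those called lower 1484, and all tested genes 3284. The slope of log2 CPM per 10-fold of length was 0.483 ± 0.102 in Palb and -0.477 ± 0.167 in Vehicle (SD, n = 4; exact permutation p = 0.02857, the smallest possible; adjusted 0.04286). It was 0.41 ± 0.295 in Fulv, -0.001 ± 0.227 in Fulv+Palb and -0.112 ± 0.0428 in Fulv+NAMPTi (SD, n = 4), each with the same exact permutation p against Vehicle. The slopes of NAMPTi (-0.228 ± 0.529, exact permutation p = 0.3714) and Palb+NAMPTi (-0.0746 ± 0.231, exact permutation p = 0.05714) did not pass. In Fulv, genes called higher had a median transcript of 5777 bases and those called lower 1677. Of 81 ribosomal protein genes, a short class picked out after the data were seen, 73 fell in Palb against Vehicle, with a median log2 fold change of -1.19. With the length trend removed 43 fell, with a median of -0.80. In that fit Hipk2 (1.53), Zbtb16 (2.20), Fasn (1.63), Rps14 (-1.68) and Rpl39 (-1.23) still passed in edgeR, with adjusted p-values of 0.0021, 0.048, 0.046, 0.0074 and 0.023. Pcsk9 (1.40), Acly (0.92) and Acaca (0.58) did not, at 0.063, 0.12 and 0.41.

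For Palb against Vehicle edgeR called 3098 human genes, 1284 higher and 1814 lower, and 1906 mouse genes, 807 higher and 1099 lower. Of the 22 mouse results of genes named by rule, 12 passed whichever library was left out; the mouse count was 2865 without Vehicle 2, 1172 without Vehicle 3 (588 higher, 584 lower), 1200 without Palb 1, 911 without Palb 2 and 972 without Palb 4, and the human count was 2004 without Vehicle 3, 1763 without Palb 2 and 1779 without Palb 4. In edgeR fits with the length slope of mouse genes as a covariate both counts were 0. That slope ran from 0.356 to 0.597 in Palb and from -0.638 to -0.245 in Vehicle. It parts the 2 groups, so these fits cannot tell a length trend from an effect of the drug.

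NAMPTi against Vehicle asked what KPT-9274 alone changed. In the mouse tissue edgeR called 1 gene, the retinoid-binding protein gene Rbp3, which rose by 3.86 ± 0.604 on the log2 scale (SE; edgeR adjusted p = 0.014; chosen after its value was seen). At an unadjusted p under 0.05 there were 2378 genes, DESeq2 called 360 and limma-trend 1. Macrophage genes had a median log2 fold change of -0.86 (camera adjusted p = 3.1e-06), acute phase genes -0.64 (camera adjusted p = 0.013) and cholesterol and fatty acid synthesis genes 0.51 (camera adjusted p = 0.018), with no member past edgeR's test in any of them. With an estimated correlation these adjusted p-values were 0.69, 0.84 and 0.84. Beside these lists, the human share was 86.0% in NAMPTi and 73.0% in Vehicle. Once the human to mouse ratio was a covariate, camera's adjusted p was 0.76 for acute phase genes, with the direction turned, and the other 2 lists still passed in the same direction. Lists that had not passed before then did. The hepatocyte, gluconeogenesis, NAD, xenobiotic and fatty acid oxidation lists were higher (camera adjusted p = 5.3e-06, 3.6e-09, 2.8e-05, 0.00077 and 0.02). The fibroblast, neutrophil, interferon and cell cycle lists were lower (camera adjusted p = 0.0017, 0.0017, 0.014 and 0.02). Without the covariate the interferon list had a median of -0.09 while its test pointed up (camera adjusted p = 0.92).

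In the tumour cells edgeR called 985 genes, 433 higher and 552 lower, for NAMPTi against Vehicle. Which direction had more calls depended on the fit: limma-trend gave 559 higher and 357 lower, and edgeR gave 252 higher and 90 lower without NAMPTi 1 and 267 higher and 238 lower without NAMPTi 3. This count rested on single libraries: it was 3112 without Vehicle 1, 3793 without Vehicle 2, 98 without Vehicle 3, 7 without Vehicle 4, 342 without NAMPTi 1, 2108 without NAMPTi 2, 505 without NAMPTi 3 and 13 without NAMPTi 4. The mouse count was 46 without Vehicle 1, 96 without Vehicle 2, 15 without Vehicle 3, 1439 without NAMPTi 2, and 0 in edgeR without Vehicle 4, NAMPTi 1 or NAMPTi 3.

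Fulv+Palb against Vehicle asked what fulvestrant and palbociclib changed together. The male-biased liver genes were higher again: Cyp4a12a rose by 7.71 ± 1.3 (SE; edgeR adjusted p = 0.0047), to 55.5 ± 59.3 CPM (SD, n = 4), and Mup20 by 4.44 ± 0.79 (SE; edgeR adjusted p = 0.0047), to 198 ± 148 CPM. Srd5a1, a steroid reductase, rose by 2.67 ± 0.42 and the liver transcription factor gene Onecut1 by 3.47 ± 0.58 (SE; edgeR adjusted p = 0.0034 and 0.0041). Cyp3a16 was lower by a ratio of 129 (95% counting interval 35.4 to 1070) and Cyp3a41a by 78.7 (26.7 to 383). These ratios were 33.2 and 44.9 without Vehicle 2 and 80.9 and 49.5 without Fulv+Palb 1. Without Fulv+Palb 2 Cyp3a16 had a bound of 68.3 and Cyp3a41a a ratio of 188. Of the sex-biased lists drawn up after the data were seen, 12 of 13 male-biased genes rose and 9 of 18 female-biased genes fell, with medians of 3.04 and -2.93. Nmrk1, a kinase that makes NAD from nicotinamide riboside, rose by 1.49 ± 0.28 (SE; edgeR adjusted p = 0.0051), from 11.1 ± 4.92 to 31.6 ± 8.94 CPM (SD, n = 4), and was the 1 of 20 NAD genes that did (camera adjusted p = 0.01, and adjusted p = 0.71 with an estimated correlation).

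In the same comparison 6 of 20 interferon response genes fell (17 adjusted over the list alone). The antiviral genes Isg15 and Mx1 had log2 fold changes of -1.60 ± 0.39 and -1.56 ± 0.39, and the regulator Irf7 one of -0.98 ± 0.22 (SE; edgeR adjusted p = 0.019, 0.023 and 0.014). Camera gave an adjusted p of 1.1e-09, and it was 0.62 with an estimated correlation. S100a9 (-2.15 ± 0.61, SE; edgeR adjusted p = 0.036) was the 1 of 6 neutrophil genes that fell (5 adjusted over the list alone; camera adjusted p = 0.0049, and adjusted p = 0.62 with an estimated correlation). Macrophage genes had a median log2 fold change of -0.81 (4 of 13 lower adjusted over the list alone; camera adjusted p = 0.028), gluconeogenesis genes one of 0.71 (camera adjusted p = 0.03) and cholesterol and fatty acid synthesis genes one of 0.30 (camera adjusted p = 0.031). None of their members passed edgeR's test over all genes, and the adjusted p was 0.71 with an estimated correlation for each. The macrophage list did not pass with the human to mouse ratio as a covariate (camera adjusted p = 0.13). In that fit the hepatocyte, xenobiotic and fatty acid oxidation lists newly passed as higher (camera adjusted p = 0.00017, 0.00046 and 0.0035). The fibroblast and ATF4 stress response lists newly passed as lower (camera adjusted p = 0.0021 and 0.04). For Fulv+Palb against Vehicle edgeR called 5534 human genes, 2476 higher and 3058 lower, and 900 mouse genes, 406 higher and 494 lower. Of the 25 mouse results of genes named by rule, 10 passed whichever library was left out, and the mouse count was 2076 without Vehicle 2, 237 without Vehicle 3 (147 higher, 90 lower), 131 without Fulv+Palb 1 (87 higher, 44 lower) and 390 without Fulv+Palb 3 (235 higher, 155 lower), so the direction with more calls was not stable. In an edgeR fit of the compared groups alone it was 1.

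Fulv+NAMPTi against Vehicle asked what KPT-9274 with fulvestrant changed. Interferon response genes showed the most calls of any list in this comparison, with 14 of 20 lower (18 adjusted over the list alone). Isg15 had a log2 fold change of -1.68 ± 0.39, Mx1 one of -1.57, Ifit3 one of -1.29 and Rsad2 one of -1.25 (SE; edgeR adjusted p = 0.014 for Isg15). Camera gave an adjusted p of 2e-11, and it was 0.48 with an estimated correlation. In the ATF4 stress response list 4 of 20 genes fell (8 adjusted over the list alone, 7 lower and 1 higher), among them the stress regulators Nupr1 by -1.45 ± 0.4, Ddit3 by -0.65 and Atf4 itself by -0.56 (camera adjusted p = 0.016, and adjusted p = 0.57 with an estimated correlation). Timp1, an inhibitor of matrix proteases, fell by 2.51 ± 0.66 (edgeR adjusted p = 0.025) and was the 1 of 14 fibroblast genes past the test (3 adjusted over the list alone; camera adjusted p = 0.008, and adjusted p = 0.57 with an estimated correlation). Nmrk1 rose by 1.66 ± 0.28 (SE; edgeR adjusted p = 0.0028), to 35.7 ± 5.53 CPM (SD, n = 4), 1 of 20 NAD genes past the test (5 adjusted over the list alone; camera adjusted p = 6.6e-05, and adjusted p = 0.57 with an estimated correlation). Further lists passed camera's test with no member past edgeR's. Neutrophil genes had a median log2 fold change of -1.31 (5 of 6 lower adjusted over the list alone; camera adjusted p = 0.012, and adjusted p = 0.57 with an estimated correlation) and gluconeogenesis genes one of 0.92 (camera adjusted p = 0.0014, and adjusted p = 0.57 with an estimated correlation). The medians were 0.37 for hepatocytes, 0.31 for fatty acid oxidation and 0.29 for cholesterol and fatty acid synthesis (camera adjusted p = 0.034, 0.02 and 0.011; 0.72, 0.7 and 0.7 with an estimated correlation).

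The sex-biased liver genes moved in this pair too. Cyp4a12a rose by 6.97 ± 1.3 and Mup20 by 4.25 ± 0.78 (SE; edgeR adjusted p = 0.0061 and 0.0053), to 33.5 ± 26.9 and 173 ± 105 CPM (SD, n = 4). Sult3a1 had a log2 fold change of -5.12 ± 1.2 (SE), at 4.78 ± 7.95 CPM, and Cyp3a41a was lower by a ratio of 288 (95% counting interval 51.4 to 11400), which was 164 without Vehicle 2 and a bound of 66.1 without Fulv+NAMPTi 3. Of the lists drawn up after the data were seen, 12 of 13 male-biased genes rose and 9 of 18 female-biased genes fell, with medians of 2.92 and -2.84. Cyp2b10, a target of the xenobiotic receptor CAR, rose by 2.67 ± 0.66 (SE; edgeR adjusted p = 0.019) and was the 1 of 16 xenobiotic genes that did (camera adjusted p = 0.011, and adjusted p = 0.57 with an estimated correlation). For Fulv+NAMPTi against Vehicle edgeR called 5446 human genes, 2328 higher and 3118 lower, and 994 mouse genes, 399 higher and 595 lower. Of the 27 mouse results of genes named by rule, 12 passed whichever library was left out, and the mouse count was 636 without Vehicle 1, 2187 without Vehicle 2, 279 without Vehicle 3 (151 higher, 128 lower), 176 without Fulv+NAMPTi 1 (111 higher, 65 lower), 367 without Fulv+NAMPTi 2 (197 higher, 170 lower), 239 without Fulv+NAMPTi 3 (151 higher, 88 lower) and 635 without Fulv+NAMPTi 4 (319 higher, 316 lower), so the direction with more calls was not stable. In an edgeR fit of the compared groups alone it was 122.

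Palb+NAMPTi against Vehicle asked the same of the pair without fulvestrant. Of the interferon genes, 5 of 20 fell (15 adjusted over the list alone): Oas2 had a log2 fold change of -1.33 ± 0.3, Oasl2 one of -1.23 ± 0.25 and Irf7 one of -1.05 ± 0.22 (SE; edgeR adjusted p = 0.042, 0.025 and 0.029). Camera gave an adjusted p of 5.6e-15, and it was 0.23 with an estimated correlation. Mcm6, a part of the replication helicase, rose by 0.82 ± 0.19 (SE; edgeR adjusted p = 0.046), 1 of 22 cell cycle genes past the test (9 adjusted over the list alone; camera adjusted p = 3e-10, and adjusted p = 0.43 with an estimated correlation). Nmrk1 rose by 1.37 ± 0.28 (SE; edgeR adjusted p = 0.026), to 29.3 ± 6.01 CPM (SD, n = 4), as did the clock repressor gene Cry1 by 1.24 ± 0.22 and the cell cycle kinase gene Wee1 by 1.25 ± 0.22 (SE). Gpnmb, a glycoprotein of lipid-laden macrophages, fell by 2.44 ± 0.47 and the chemokine gene Ccl3 by 2.42 ± 0.47 (SE). Nmrk1 was the 1 of 20 NAD genes past the test (camera adjusted p = 0.031, and adjusted p = 0.68 with an estimated correlation). Lists with no member past edgeR's test also passed in camera. The median log2 fold changes were -0.47 for macrophages, -0.78 for neutrophils, -0.28 for endothelial cells and 0.65 for cholesterol and fatty acid synthesis (camera adjusted p = 0.03, 0.038, 0.047 and 7.8e-06). With an estimated correlation these adjusted p-values were 0.59, 0.57, 0.57 and 0.57. The sex-biased lists had 0 of 13 and 0 of 18 genes past edgeR's test, with medians of 0.26 and 0.27.

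For Palb+NAMPTi against Vehicle edgeR called 1542 human genes, 699 higher and 843 lower, and 66 mouse genes, 32 higher and 34 lower. None of the 19 mouse results of genes named by rule passed whichever library was left out: the mouse count was 27 without Vehicle 1, 354 without Vehicle 2, 142 without Vehicle 3 (82 higher, 60 lower), 106 without Vehicle 4, 3 without Palb+NAMPTi 3, 33 without Palb+NAMPTi 4 and 0 in edgeR without Palb+NAMPTi 2. The human count was 859 without Vehicle 1, 2660 without Vehicle 2, 237 without Palb+NAMPTi 2 (133 higher, 104 lower) and 931 without Palb+NAMPTi 3 (483 higher, 448 lower), and without Vehicle 3 there were 1039 higher and 821 lower.

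Fulv+NAMPTi against Fulv asked what the NAMPT inhibitor added to fulvestrant. Metabolic liver genes were higher in the pair. Of the 2649 mouse genes called, 99.9% had the same direction in Fulv+Palb against Fulv, at a median of 0.759. Against Vehicle, 69% had that direction in Fulv+Palb (median 0.224), 87.4% in Fulv+NAMPTi (0.436) and 6.46% in Fulv (-0.565). Both pairs were compared with the same Fulv libraries, so the agreement between them follows in part from that. Gluconeogenesis and amino acid catabolism had 10 of 14 genes higher (14 adjusted over the list alone), with Pck1, which controls gluconeogenesis, up by 3.12 ± 0.75 (SE; edgeR adjusted p = 0.013), from 260 ± 108 to 2260 ± 1150 CPM (SD, n = 4), and the tyrosine-degrading Tat by 2.89 ± 0.69 (SE; edgeR adjusted p = 0.012). NAD metabolism had 10 of 20 higher (14 adjusted over the list alone), with Nmrk1 up by 2.20 ± 0.31 (SE; edgeR adjusted p = 0.00077), from 7.71 ± 1.67 to 35.7 ± 5.53 CPM (SD, n = 4), the tryptophan-degrading Tdo2 by 2.06 and Acmsd by 2.47. Fatty acid oxidation had 9 of 16 higher (13 adjusted over the list alone; Cyp4a10 by 4.78 ± 1.2, Acox1 by 1.97), xenobiotic metabolism 7 of 16 (9 adjusted over the list alone; Cyp2b10 by 4.76 ± 0.89) and hepatocytes 7 of 17 (10 adjusted over the list alone; Cps1 by 2.56, Cyp2e1 by 2.19).

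Matrix genes were lower in the same comparison. Of 14 fibroblast and stellate genes 8 fell (11 adjusted over the list alone, 10 lower and 1 higher). Col1a1, the main fibrillar collagen, had a log2 fold change of -2.17 ± 0.53 (SE; edgeR adjusted p = 0.013), from 8340 ± 2170 to 1850 ± 491 CPM (SD, n = 4), and the smooth muscle actin gene Acta2 one of -1.54 ± 0.36 (SE). Has2, a hyaluronan synthase, fell by 3.19 ± 0.79 and the cytokine gene Lif by 2.57 ± 0.45 (SE; edgeR adjusted p = 0.013 and 0.0045). Camera's adjusted p-values for these 6 lists were 8.7e-09 for gluconeogenesis, 5.9e-08 for NAD, 9.3e-07 for fatty acid oxidation, 2.4e-06 for xenobiotic metabolism, 4.8e-07 for hepatocytes and 2e-06 for fibroblasts. For each of them the adjusted p was 0.33 with an estimated correlation. Cell cycle genes fell in 5 of 22 cases (11 adjusted over the list alone; Plk1 by -1.20, Cdc20 by -1.06; camera adjusted p = 2.4e-05, and adjusted p = 0.38 with an estimated correlation). Of the interferon genes 3 of 20 fell and 1 rose (5 adjusted over the list alone, 4 lower and 1 higher), with a median of -0.43 (camera adjusted p = 0.0097, and adjusted p = 0.57 with an estimated correlation). In cholesterol and fatty acid synthesis 2 of 20 rose (0 adjusted over the list alone), with a median of 0.40 (camera adjusted p = 0.012, and adjusted p = 0.57 with an estimated correlation). Beside these lists, the hepatocyte mean was 12.1 ± 0.296 log2 CPM in the pair and 10.6 ± 0.581 in Fulv, and the human share was 75.4% against 89.1%. None of these 9 lists passed with the human to mouse ratio as a covariate, with camera adjusted p-values of 0.1 to 0.96.

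For Fulv+NAMPTi against Fulv edgeR called 2649 mouse genes, 1367 higher and 1282 lower, and 0 human genes, with 1696 at an unadjusted p under 0.05, 50 by DESeq2 and 0 by limma-trend. Of the 50 mouse results of genes named by rule, 16 passed whichever library was left out; the mouse count was 350 without Fulv 2 (172 higher, 178 lower), 1425 without Fulv 3 (707 higher, 718 lower), 1654 without Fulv 4, 908 without Fulv+NAMPTi 1, 1567 without Fulv+NAMPTi 2 and 715 without Fulv+NAMPTi 3. In edgeR the mouse count was 1 with the human to mouse ratio as a covariate, 24 with the hepatocyte mean and 10 with the length slope. Each of these covariates parted Fulv+NAMPTi from Fulv without overlap, so these fits cannot tell the covariate from an effect of the drug.

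**Figure D3:**
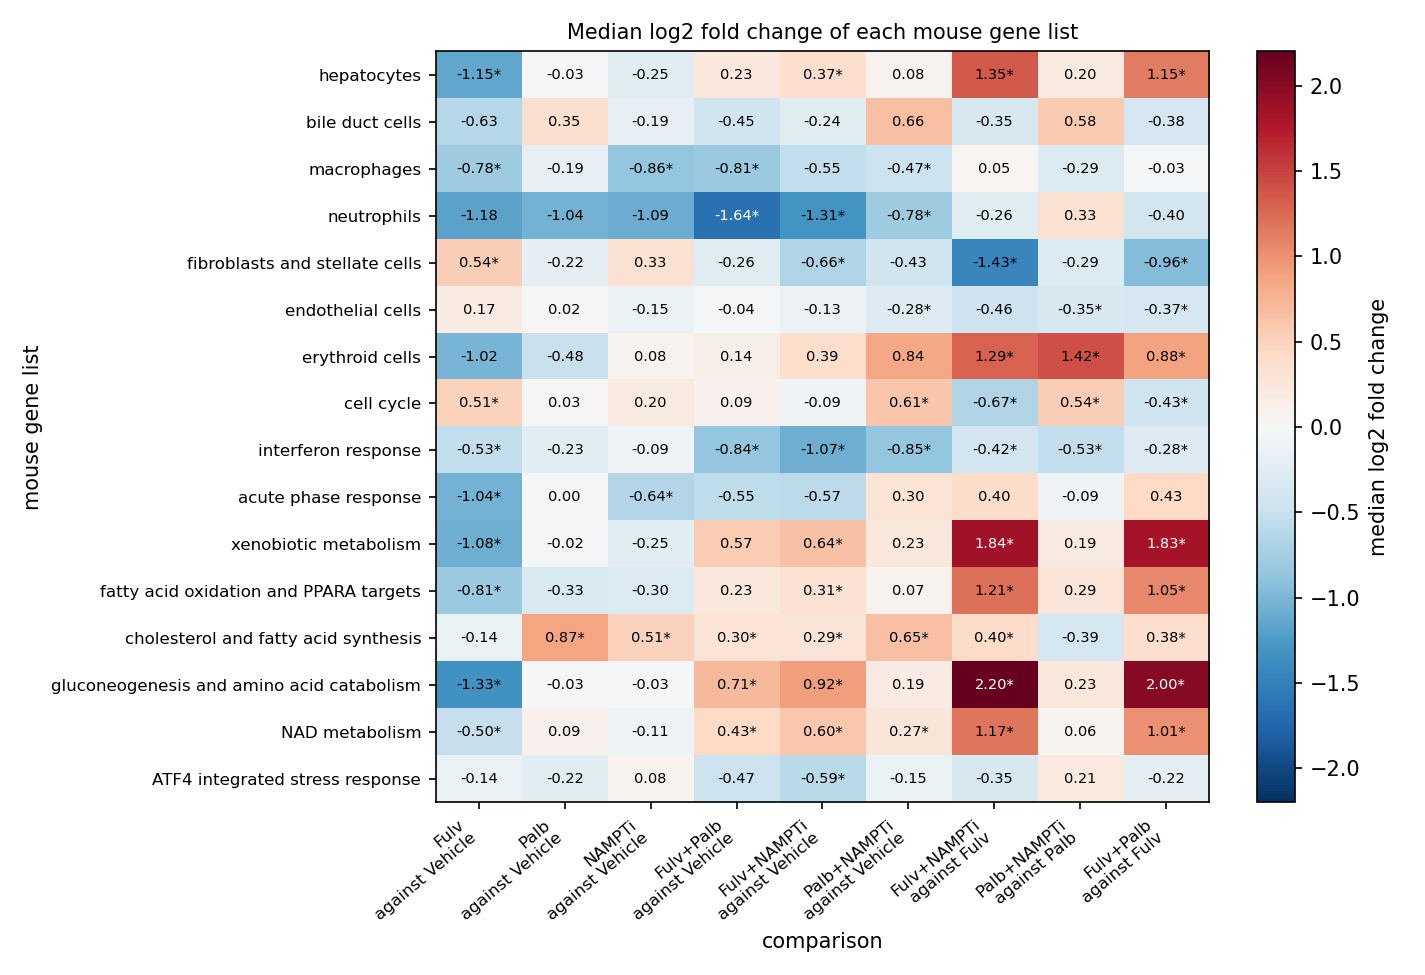
Median log2 fold change of each mouse gene list (rows) in each comparison (columns) as colour, with * for lists with a camera adjusted p under 0.05 at a preset correlation of 0.01. Interferon medians ran to -1.07 in Fulv+NAMPTi against Vehicle and gluconeogenesis to 2.20 in Fulv+NAMPTi against Fulv; no list passed with an estimated correlation.

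Palb+NAMPTi against Palb asked what the NAMPT inhibitor added to palbociclib. Nnmt, which methylates nicotinamide, rose by 2.14 ± 0.39 and Nmrk1 by 1.41 ± 0.28 (SE; edgeR adjusted p = 0.021 and 0.029). They were 2 of 20 NAD genes, and that list did not pass, with a median of 0.06 (camera adjusted p = 0.26, and adjusted p = 0.97 with an estimated correlation). High Nmrk1 did not go with the NAMPT inhibitor alone. Its mean was 13.2 ± 5.1 CPM in NAMPTi, 11.1 ± 4.92 in Vehicle and 31.6 ± 8.94 in Fulv+Palb (SD, n = 4). The clock gene Nr1d1 had a log2 fold change of -2.53 ± 0.4 (SE; edgeR adjusted p = 0.014), from 131 ± 43.6 to 22.8 ± 8.1 CPM (SD, n = 4), while Cry1 rose by 1.33 ± 0.22 (SE). Of the interferon genes 2 of 20 fell, Oasl2 by -1.18 ± 0.25 and Mx2 by -0.99 ± 0.18 (11 adjusted over the list alone, 10 lower and 1 higher; camera adjusted p = 3.8e-08, and adjusted p = 0.54 with an estimated correlation). The cell cycle list had none of 22 past edgeR's test (8 adjusted over the list alone; camera adjusted p = 2.6e-08, and adjusted p = 0.54 with an estimated correlation).

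For Palb+NAMPTi against Palb edgeR called 1394 human genes, 764 higher and 630 lower, and 31 mouse genes, 17 higher and 14 lower. None of the 16 mouse results of genes named by rule passed whichever library was left out: the mouse count was 10 without Palb 1, 79 without Palb 3, 15 without Palb+NAMPTi 1, 15 without Palb+NAMPTi 2, 1 without Palb+NAMPTi 4 and 0 in edgeR without Palb 2 or Palb 4. The human count was 722 without Palb 1, 292 without Palb 2, 924 without Palb 3, 361 without Palb 4 and 199 without Palb+NAMPTi 4.

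Fulv+Palb against Fulv asked what palbociclib added to fulvestrant. Xenobiotic genes rose in 4 of 16 cases (8 adjusted over the list alone), among them Cyp2b10 by 3.80 ± 0.92 and Cyp3a11, a main drug-metabolising enzyme, by 2.76 ± 0.65 (SE; edgeR adjusted p = 0.043 and 0.041; camera adjusted p = 9.5e-07, and adjusted p = 0.36 with an estimated correlation). Pck1 and Tat, 2 of 14 gluconeogenesis genes (14 adjusted over the list alone), rose by 3.01 ± 0.75 and 2.99 ± 0.69 (SE; edgeR adjusted p = 0.048 and 0.04; camera adjusted p = 3.4e-09, and adjusted p = 0.36 with an estimated correlation). Nmrk1 and Nampt, 2 of 20 NAD genes (10 adjusted over the list alone), rose by 2.04 ± 0.31 and 1.20 ± 0.27 (SE; camera adjusted p = 2.5e-07, and adjusted p = 0.36 with an estimated correlation). Cell type lists differed too. Of 17 hepatocyte genes 1 rose (7 adjusted over the list alone), with a median of 1.15 (camera adjusted p = 3.3e-07, and adjusted p = 0.38 with an estimated correlation). No fibroblast gene of 14 passed in edgeR over all genes (10 adjusted over the list alone, 9 lower and 1 higher), with a median of -0.96 (camera adjusted p = 2.8e-05, and adjusted p = 0.36 with an estimated correlation). Lists with no member past edgeR's test over all genes also passed in camera. They were fatty acid oxidation (12 of 16 higher adjusted over the list alone; median 1.05), cell cycle (median -0.43), interferon response (-0.28) and cholesterol and fatty acid synthesis (1 of 20 higher adjusted over the list alone; 0.38). Their camera adjusted p-values were 4.2e-07, 0.0022, 0.016 and 0.0092, and 0.36, 0.57, 0.58 and 0.58 with an estimated correlation. Beside these lists, the hepatocyte mean was 11.9 ± 0.629 log2 CPM in the pair and 10.6 ± 0.581 in Fulv (SD, n = 4), and the human share was 80.5% against 89.1%. The xenobiotic, gluconeogenesis and fatty acid oxidation lists still passed with the human to mouse ratio as a covariate (camera adjusted p = 0.021 each). The hepatocyte (0.58), NAD (0.057), fibroblast (0.051), cell cycle (0.98), interferon (0.8) and cholesterol (0.58) lists did not. With the hepatocyte mean as a covariate 7.04% of the 142 calls stayed, the median size of their log2 fold change going from 1.30 to 0.85 and the median SE from 0.279 to 0.244, and all 142 kept their sign. The plasminogen activator gene Plat fell by 1.77 ± 0.29 and Nr1d1 by 2.05 ± 0.4 (SE; edgeR adjusted p = 0.0061 and 0.022).

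For Fulv+Palb against Fulv edgeR called 142 mouse genes, 109 higher and 33 lower, and 0 human genes, with 974 at an unadjusted p under 0.05, 3 by DESeq2 and 0 by limma-trend. Of the 23 mouse results of genes named by rule, that of Nmrk1 alone passed whichever library was left out: the mouse count was 7 without Fulv 2, 9 without Fulv 3, 8 without Fulv 4, 5 without Fulv+Palb 1, 47 without Fulv+Palb 2, 9 without Fulv+Palb 3 and 1523 without Fulv+Palb 4. Human counts were 1 without Fulv+Palb 2 and 1 without Fulv+Palb 3.

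**Figure D4:**
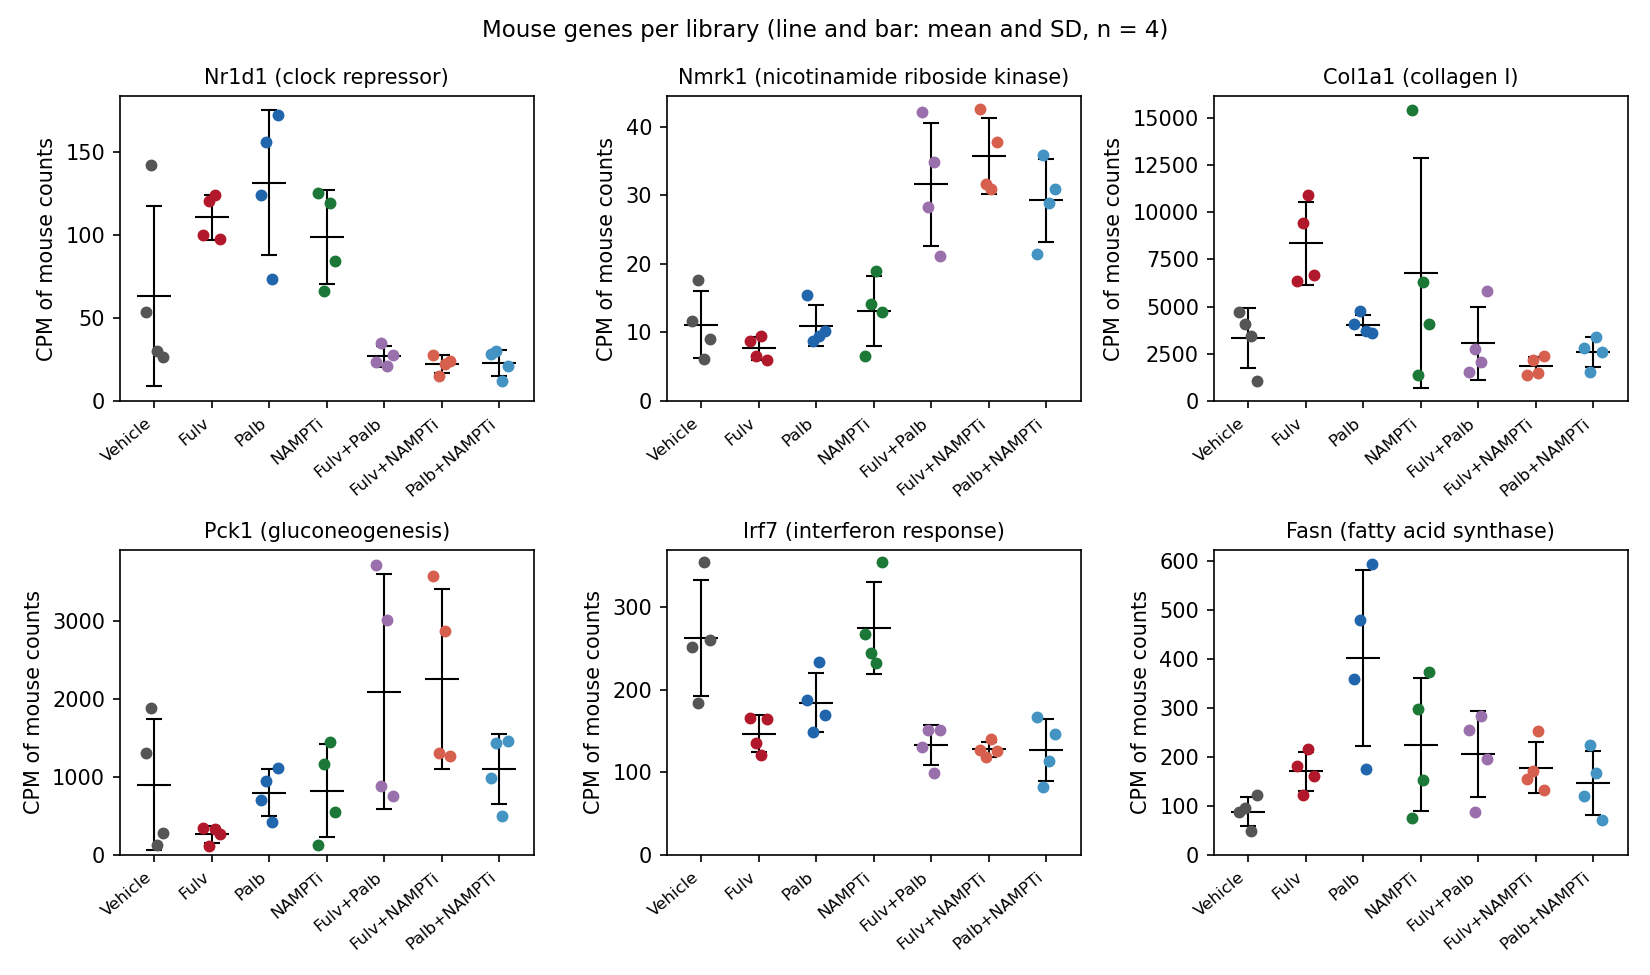
CPM of mouse genes (y axis) of Nr1d1, Nmrk1, Col1a1, Pck1, Irf7 and Fasn in each library by group, with the mean and SD of 4 libraries. Mean Nr1d1 was 22.3 to 26.7 CPM in the groups with a pair of drugs and 62.9 to 131 CPM in the others.

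The interaction terms asked whether the second drug changed the tumour cells differently on top of the first than alone. edgeR called 826 human genes for Fulv and NAMPTi (451 higher, 375 lower), 2856 for Palb and NAMPTi (1756 higher, 1100 lower) and 1156 for Fulv and Palb (726 higher, 430 lower). For Fulv and NAMPTi the count was 2957 without Vehicle 1, 3289 without Vehicle 2, 12 without Vehicle 3, 10 without Vehicle 4, 60 without Fulv 2, 2 without Fulv 3, 6 without Fulv 4, 111 without NAMPTi 1 (37 higher, 74 lower), 2263 without NAMPTi 2, 470 without NAMPTi 3 (229 higher, 241 lower), 29 without NAMPTi 4, 381 without Fulv+NAMPTi 1, 7 without Fulv+NAMPTi 2, 514 without Fulv+NAMPTi 3 and 2 without Fulv+NAMPTi 4. For Palb and NAMPTi it was 4557 without Vehicle 2, 1429 without Vehicle 3, 1691 without Palb 2, 1903 without Palb 4 and 1511 without Palb+NAMPTi 4. For Fulv and Palb it was 2889 without Vehicle 2, 358 without Vehicle 3 (159 higher, 199 lower), 224 without Fulv 2 (107 higher, 117 lower), 77 without Fulv 3 (31 higher, 46 lower), 641 without Fulv 4, 385 without Palb 1, 143 without Palb 2 (62 higher, 81 lower), 272 without Palb 4, 747 without Fulv+Palb 1, 390 without Fulv+Palb 2, 481 without Fulv+Palb 3 and 733 without Fulv+Palb 4. In edgeR fits with the length slope of mouse genes as a covariate all 3 counts were 0. The slope differed between groups, so these fits cannot tell a length trend from an effect of the drugs.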

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

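Tests chosen only after the result was seen were those of male animals, of the human to mouse ratio for the female-biased genes in Fulv, of less liver RNA in the Fulv libraries, of the time of collection, and of the ratio for the length pattern. The sex-biased and clock gene lists and the hepatocyte and length alternatives were also chosen after seeing the data, while the splits of the samples were planned.

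Of 91 groups of 4 libraries looked at, 3 had 1 library far from the rest, and chance gives about 1 in 20. Cyp4a12a was 0.279 CPM in NAMPTi 3 and 0 in the other NAMPTi libraries, but this was 1 count, which always stands apart from 3 values of 0 and so says nothing of that library. Mup20 was 61.1 CPM in Palb 1 and 6.14 to 9.37 in the other Palb libraries. Sult3a1 was 16.6 CPM in Fulv+NAMPTi 3 and 0 to 2.19 in the others of its group. edgeR's interaction test on human genes called 826 for Fulv and NAMPTi, 2856 for Palb and NAMPTi and 1156 for Fulv and Palb. With 1 library left out these counts ranged from 2 to 3289, from 1429 to 4557 and from 77 to 2889. The splits of the samples cannot tell whether chance gave these calls.

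In the 3 groups with fulvestrant, male-biased liver genes were higher and female-biased genes lower than in Vehicle. Male animals in those groups were argued against by 0 counts on 4 Y-linked genes in all 12 libraries. For the male-biased genes in Fulv+Palb and Fulv+NAMPTi, a different share of hepatocyte RNA and a different human to mouse ratio were argued against too. The lower of the medians of these groups was 2.49 with the hepatocyte mean as a covariate and 3.21 with the ratio. Fulv was not part of that test, and its median was 2.47 and 3.10 in those fits and 1.85 without a covariate. For the female-biased genes in Fulv the ratio as the whole cause was argued against: the 3 libraries without fulvestrant at as high a human share (NAMPTi 1, 3 and 4) each had a higher median log2 CPM of these genes than every Fulv library, and their mean was 4.28 above that of Fulv (3.55 ± 1.78 and -0.734 ± 1.1, SD). A part of the fold stays open, since with the ratio as a covariate the median went from -6.06 to -3.26 and edgeR called 0 of the 18 genes. With the ratio the median of these genes was -1.91 in Fulv+Palb and -2.37 in Fulv+NAMPTi. With the hepatocyte mean as a covariate it was -4.64 in Fulv, -3.36 in Fulv+Palb and -3.32 in Fulv+NAMPTi. Loss of estrogen signalling in the host liver under fulvestrant may account for the pattern and was not tested.

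In Fulv+NAMPTi, metabolic liver genes were higher and matrix genes lower than in Fulv. A candidate explanation is less liver RNA in the Fulv libraries: with the hepatocyte mean as a covariate 0.755% of the 2649 calls stayed, the median size of the log2 fold change going from 1.00 to 0.47 and the median SE from 0.284 to 0.233. That covariate also parts the groups, so an effect of the drug on liver genes is not excluded. Nr1d1, a clock gene, differed as far in Palb+NAMPTi against Palb (-2.53) as here (-2.31). Signed by their direction here, the 2649 genes had a median there of 0.273 (quartiles 0.0655 and 0.483) against 1.00 here (0.729 and 1.43), and 81% kept their sign. In Fulv+Palb against Fulv, which shares the Fulv libraries, Nr1d1 differed by -2.05 and the genes had a median of 0.759, with 99.9% of the same sign. In Fulv against Vehicle their median was -0.565. The genes were picked by their values here, so a smaller median elsewhere follows in part from that choice. The time of collection as a whole or partial cause therefore stays open, and no label gives a time.

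Long transcripts were higher and short ones lower in Palb than in Vehicle. A different human to mouse ratio was argued against, since 92.2% of the 1906 calls stayed with it as a covariate. A length trend between libraries as the whole cause cannot be told apart from an effect of the drug: 18.4% of the calls stayed with the trend removed, the median fold going from 0.80 to 0.48 and the median SE from 0.205 to 0.188, and the trend parts the groups. It was not particular to palbociclib, as Vehicle stood apart from Fulv as well, where 21.5% of the 1353 calls stayed with the trend removed and the median fold went from 0.83 to 0.58 (median SE 0.225 and 0.204). Hipk2, Zbtb16, Fasn, Rps14 and Rpl39 still passed in Palb against Vehicle, and an effect of palbociclib on the host stays open.

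Other splits of the same libraries were fitted to see how often they gave as many genes. The real split counts among them, so 1 of 35 is the smallest share for a pair of groups. The shares were not adjusted over the comparisons, so a share under 1 in 20 does not exclude chance. For human genes no other split gave as many for Fulv (5281 genes, highest other split 3741), Palb (3098, 2837), Fulv+Palb (5534, 3217) and Fulv+NAMPTi (5446, 3217) against Vehicle. The same was true of Palb+NAMPTi against Palb (1394, 0). For the interactions all labels of the groups involved were exchanged, which also breaks up the effects of the single drugs. These splits therefore cannot tell whether chance gave the interaction calls. As many genes came up in 3 of 100 splits for Palb and NAMPTi (2856, 3701), 1 of 100 for Fulv and Palb (1156, 298) and 7 of 100 for Fulv and NAMPTi (826, 4094). Other splits reached the real count for NAMPTi (8 of 35, 985, 5591) and Palb+NAMPTi against Vehicle (5 of 35, 1542, 2390). For Fulv+NAMPTi against Fulv (35 of 35; 0; 0) and Fulv+Palb against Fulv (35 of 35; 0; 6) the real count was 0 in edgeR. The split with 5591 genes set NAMPTi 1 and 3 with Vehicle 1 and 2 against the rest, several times the real count, which points to a structure of these samples apart from treatment.

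For mouse genes no other split gave as many for Fulv (1353, 591), Fulv+NAMPTi (994, 156) and Palb+NAMPTi (66, 18) against Vehicle (1 of 35 each). The same was true of Fulv+NAMPTi against Fulv (2649, 0), Palb+NAMPTi against Palb (31, 0) and Fulv+Palb against Fulv (142, 112). Being the smallest share possible, 1 of 35 does not exclude chance here either. Other splits reached the real count for Palb (2 of 35, 1906, 1914), NAMPTi (18 of 35, 1, 3109) and Fulv+Palb (3 of 35, 900, 1145) against Vehicle. The number of gene lists past camera's test was reached by other splits in every comparison. It was 10 for Fulv (3 of 35 splits; highest other 12), 1 for Palb (34; 10), 3 for NAMPTi (32; 12), 6 for Fulv+Palb (24; 10), 10 for Fulv+NAMPTi (4; 10) and 7 for Palb+NAMPTi (25; 11) against Vehicle. It was 10 for Fulv+NAMPTi against Fulv (14; 12), 4 for Palb+NAMPTi against Palb (29; 13) and 11 for Fulv+Palb against Fulv (9; 13).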

How the results depend on the processing

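The tests with the hepatocyte mean or the length slope as a covariate, with the length trend removed or without Vehicle 3 and 4, and the mouse comparisons with a single agent, were chosen after seeing the data. Counts are of genes called by edgeR unless another tool is named. A count is given where it was over 1.5 times above or below that of the report. Where a count moved, the cause was not tested, except that the 2-group fit and the fit without Vehicle 3 and 4 used fewer samples.

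With 1 library left out, human counts ranged from 3955 to 6852 for Fulv+Palb and 4157 to 6703 for Fulv+NAMPTi against Vehicle, 0 to 0 for Fulv+NAMPTi against Fulv and 0 to 1 for Fulv+Palb against Fulv. The other human counts ranged from 3394 to 6948 for Fulv, 1763 to 4495 for Palb, 7 to 3793 for NAMPTi and 237 to 2660 for Palb+NAMPTi against Vehicle, 199 to 1186 for Palb+NAMPTi against Palb, and 2 to 3289, 1429 to 4557 and 77 to 2889 for the interactions of Fulv and NAMPTi, Palb and NAMPTi, and Fulv and Palb. Mouse counts ranged from 228 to 1831 for Fulv, 911 to 2865 for Palb, 0 to 1439 for NAMPTi, 131 to 2076 for Fulv+Palb, 176 to 2187 for Fulv+NAMPTi and 0 to 354 for Palb+NAMPTi against Vehicle. They ranged from 350 to 2462 for Fulv+NAMPTi against Fulv, 0 to 79 for Palb+NAMPTi against Palb and 5 to 1523 for Fulv+Palb against Fulv. The difference in human share from Vehicle ranged from 13.5 to 19.3 points for Fulv, -8.07 to -2.24 for Palb, 10.3 to 16.4 for NAMPTi, 4.86 to 10.9 for Fulv+Palb, -0.436 to 5.53 for Fulv+NAMPTi and -2.55 to 3.27 for Palb+NAMPTi.

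With DESeq2, human counts were 1941 for NAMPTi against Vehicle, 50 for Fulv+NAMPTi against Fulv, 2161 for Palb+NAMPTi against Palb, 3 for Fulv+Palb against Fulv, 2008 for the interaction of Fulv and NAMPTi and 1929 for that of Fulv and Palb. Its mouse counts were 2042 for Fulv, 360 for NAMPTi, 1441 for Fulv+Palb, 1618 for Fulv+NAMPTi and 541 for Palb+NAMPTi against Vehicle, 583 for Palb+NAMPTi against Palb and 1206 for Fulv+Palb against Fulv. RLE factors gave 2 mouse genes for NAMPTi against Vehicle. Without a low-count filter, human counts were 9 for Fulv+NAMPTi against Fulv, 5 for Fulv+Palb against Fulv and 668 for the interaction of Fulv and Palb, and mouse counts were 735 for Fulv, 1241 for Palb, 5 for NAMPTi and 36 for Palb+NAMPTi against Vehicle and 294 for Fulv+Palb against Fulv. limma-trend moved no count this far, but with it the direction that held more calls turned for human genes in NAMPTi (559 higher, 357 lower), Fulv+Palb (2924, 2743) and Palb+NAMPTi against Vehicle (722, 604) and in the interaction of Fulv and NAMPTi (397, 502). They did so for mouse genes in Fulv+Palb (363, 342), Fulv+NAMPTi (373, 335) and Palb+NAMPTi against Vehicle (29, 28).

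Over all alternatives and libraries left out, the direction with more calls turned in some of the fits with calls. For human genes these were 1 of 17 for Fulv, 8 of 15 for NAMPTi, 2 of 17 for Fulv+Palb and 7 of 17 for Palb+NAMPTi against Vehicle and 5 of 21 and 5 of 23 for the interactions of Fulv and NAMPTi and of Fulv and Palb. For mouse genes they were 4 of 18 for Fulv, 3 of 18 for Palb, 1 of 12 for NAMPTi, 8 of 19 for Fulv+Palb, 9 of 19 for Fulv+NAMPTi and 10 of 17 for Palb+NAMPTi against Vehicle and 4 of 18 for Fulv+NAMPTi against Fulv. Among them were Fulv+Palb (834 higher, 689 lower) and Fulv+NAMPTi (556, 506) with the hepatocyte mean as a covariate, Fulv with the human to mouse ratio (555, 1072), and the interaction of Fulv and Palb without Vehicle 3 and 4 (183, 317).

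With the replicate number as a block, human counts were 588 for NAMPTi against Vehicle and 416 for the interaction of Fulv and NAMPTi, and mouse counts were 0 for NAMPTi against Vehicle and 32 for Fulv+Palb against Fulv.

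With the human to mouse ratio as a covariate, human counts were 29 for NAMPTi against Vehicle and 0 for the interaction of Fulv and NAMPTi, and mouse counts were 1020 for NAMPTi, 4158 for Fulv+Palb, 3247 for Fulv+NAMPTi and 544 for Palb+NAMPTi against Vehicle, 1 for Fulv+NAMPTi against Fulv, 698 for Palb+NAMPTi against Palb and 7 for Fulv+Palb against Fulv. For Fulv against Vehicle the mouse count was 1627, but 322 of the 1353 calls (23.8%) were among them, the median size of the log2 fold change of these 1353 going from 0.83 to 0.55 and the median SE from 0.225 to 0.272. With the hepatocyte mean as a covariate, mouse counts were 3105 for Palb, 96 for NAMPTi, 1523 for Fulv+Palb and 524 for Palb+NAMPTi against Vehicle, 24 for Fulv+NAMPTi against Fulv, 963 for Palb+NAMPTi against Palb and 13 for Fulv+Palb against Fulv.

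With the length slope of mouse genes as a covariate, human counts against Vehicle were 421 for Fulv, 0 for Palb and 133 for NAMPTi. They were 3081 for Fulv+Palb and 736 for Palb+NAMPTi against Vehicle, 117 for Palb+NAMPTi against Palb and 0 for each of the 3 interactions. Mouse counts in that fit were 0 for Fulv, 0 for Palb, 0 for NAMPTi and 365 for Fulv+Palb against Vehicle, 10 for Fulv+NAMPTi against Fulv, 1 for Palb+NAMPTi against Palb and 6 for Fulv+Palb against Fulv. The slope parted Fulv and Palb from Vehicle without overlap, so there this fit cannot tell a length trend from an effect of the drug. With the length trend removed, mouse counts were 355 for Fulv, 414 for Palb, 23 for NAMPTi, 505 for Fulv+Palb and 38 for Palb+NAMPTi against Vehicle, 10 for Palb+NAMPTi against Palb and 281 for Fulv+Palb against Fulv.

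In fits of the compared groups alone, human counts were 1712 for Fulv, 364 for Palb, 0 for NAMPTi, 2076 for Fulv+Palb, 2427 for Fulv+NAMPTi and 10 for Palb+NAMPTi against Vehicle and 3052 for Palb+NAMPTi against Palb. Mouse counts there were 21 for Fulv, 264 for Palb, 0 for NAMPTi, 1 for Fulv+Palb, 122 for Fulv+NAMPTi and 0 for Palb+NAMPTi against Vehicle, 5226 for Fulv+NAMPTi against Fulv, 1332 for Palb+NAMPTi against Palb and 1108 for Fulv+Palb against Fulv. Without Vehicle 3 and 4, human counts were 2951 for Fulv, 0 for NAMPTi and 3640 for Palb+NAMPTi against Vehicle and 0, 516 and 500 for the interactions of Fulv and NAMPTi, Palb and NAMPTi, and Fulv and Palb, and mouse counts were 776 for Palb, 0 for NAMPTi, 155 for Fulv+Palb, 220 for Fulv+NAMPTi and 657 for Palb+NAMPTi against Vehicle.

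Of 144 gene list tests 62 passed with camera's preset correlation, 0 with an estimated correlation and 15 with fry. With the human to mouse ratio as a covariate 63 passed, of which 40 were among the 62, 35 of them in the same direction. None of the hepatocyte, fibroblast, xenobiotic, fatty acid oxidation, gluconeogenesis and NAD lists then passed for Fulv+NAMPTi against Fulv (camera adjusted p = 0.41, 0.13, 0.34, 0.16, 0.53 and 0.41). With the replicate number as a block 63 passed, 61 of them among the 62. No label says that this number marks a shared mouse, day or batch, so the block cannot show that the tests are free of one. Of 212 named gene results past the test, 63 passed whichever library was left out and 11 passed under every alternative run. Over 395 results of 227 named genes, 7341 repeats gave 5955 of the same direction and side of the threshold, 1191 that fell short of it, 192 that newly passed and 3 that reversed. Those 3 were Cyp2c29 (0.28) and Cyp3a11 (0.32) in Fulv against Vehicle with the human to mouse ratio as a covariate and Fbn1 (-0.16) there with the length slope as a covariate; none passed in those fits, and the cause was not tested. Leaving out libraries under 1000000 counts of a species changed nothing, since there were 0. Alternatives that needed names of human genes were not run.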

Other observations

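The clock list, the list of breast tumour genes, the Xist value and the tests on them were chosen after seeing the data, while the cell type lists were fixed before the data were examined.

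Clock genes of the host liver differed between groups. Nr1d1, a clock repressor, was at most 34.9 CPM in the 12 libraries with a pair and at least 66.0 CPM in the 12 with a single agent, while Vehicle ran from 26.4 to 142 CPM. Nmrk1 also parted the pairs, at 21.2 CPM or more with a pair and 19.0 CPM or less in all other libraries. No label gives a time. The time of collection therefore cannot be told apart from the added drug where a pair is compared with a single agent. Npas2, a clock activator, had a log2 fold change of -4.00 ± 0.73 in Fulv+NAMPTi against Fulv (SE; edgeR adjusted p = 0.0048), where Cry1 rose by 1.44 ± 0.24 and Per2 by 1.48 ± 0.41. Of 17 clock genes, 5 rose and 2 fell in Fulv+Palb, 5 rose and 3 fell in Fulv+NAMPTi, and 2 rose and 1 fell in Palb+NAMPTi against Vehicle. Adjusted over the list alone these were 12, 12 and 8 genes. Against Vehicle edgeR called 0 in Fulv, 1 higher in Palb (Nr1d2) and 0 in NAMPTi, or 0, 1 and 5 adjusted over the list alone. With the human to mouse ratio as a covariate 6 rose and 2 fell in NAMPTi against Vehicle. Against the single agent, 6 rose and 3 fell in Fulv+NAMPTi, 2 rose and 2 fell in Palb+NAMPTi, and 2 rose and 2 fell in Fulv+Palb (14, 6 and 16 adjusted over the list alone). The calls of Fulv+NAMPTi against Fulv were lost with the ratio as a covariate, where edgeR called 0 of 17. The folds did not vanish: all 9 called genes kept their sign, the median size of their log2 fold change going from 1.51 to 0.87 and the median SE from 0.403 to 0.473. With the hepatocyte mean as a covariate 1 was higher and 2 were lower, at a median of 0.92 and a median SE of 0.364 over the 9.

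Single genes of other cell types of the liver passed in edgeR. Of 7 bile duct genes Sox9 and Cdh1, chosen after their values were seen, rose in Palb against Vehicle, by 1.39 ± 0.29 and 1.38 ± 0.29 (SE; edgeR adjusted p = 0.0038 and 0.0037; camera adjusted p = 0.29). Of 12 endothelial genes Vwf, a clotting factor also chosen after its values were seen, rose by 1.23 ± 0.33 in Fulv against Vehicle (SE; edgeR adjusted p = 0.026; 3 adjusted over the list alone; camera adjusted p = 0.15). Of 6 erythroid genes Alas2, the haem synthesis enzyme of red cell precursors and chosen in the same way, rose by 1.82 ± 0.5 in Fulv+NAMPTi against Vehicle (SE; edgeR adjusted p = 0.028; camera adjusted p = 0.07). As lists, erythroid genes passed camera's test with no member past edgeR's in Fulv+NAMPTi against Fulv, Palb+NAMPTi against Palb (4 of 6 higher adjusted over the list alone) and Fulv+Palb against Fulv. Their medians were 1.29, 1.42 and 0.88 (camera adjusted p = 0.013, 0.03 and 0.033; 0.33, 0.54 and 0.44 with an estimated correlation). Endothelial genes did so, at lower medians, in Palb+NAMPTi against Palb (2 of 12 lower adjusted over the list alone), Palb+NAMPTi against Vehicle and Fulv+Palb against Fulv (1 lower adjusted over the list alone). Their medians were -0.35, -0.28 and -0.37 (camera adjusted p = 0.0076, 0.047 and 0.032; 0.54, 0.57 and 0.47 with an estimated correlation). The lymphocyte list had too few tested genes for a test.

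In a list of 8 genes of breast tumour cells, counted on the mouse genome to look for human reads placed there, 2 genes were tested. Tff3 rose by 3.2 ± 0.85 in Fulv+Palb and by 3.76 ± 0.85 in Fulv+NAMPTi against Vehicle (SE; edgeR adjusted p = 0.026 and 0.013). Car12 had a log2 fold change of -2.32 ± 0.71 in Fulv+Palb (SE; edgeR adjusted p = 0.049) and one of -2.06 ± 0.66 in Fulv+NAMPTi against Vehicle, which did not pass (SE; edgeR adjusted p = 0.057). Mouse Xist was 7.36 CPM, from 53 counts, in Palb+NAMPTi 3 and 269 to 1120 CPM in the other libraries.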
